A study of Mus musculus with 19 samples.

How the data were processed

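Single neurons of the mouse lateral hypothalamic area were hand-picked into 19 plates of 96 wells from 7 male Agrp-IRES-Cre x Ai9 mice aged 6 to 8 weeks, and each plate is 1 sample of a single group. Per the labels, non-fluorescent cell bodies were picked from the dissected area, whose borders were read from the fluorescent axons of AGRP neurons. Libraries followed Smart-SCRB, a plate-based method in which read 1 carries the well barcode and a unique molecular identifier (UMI), and were stated to hold 135025 ± 38401 (mean ± SD) reads per cell. The deposited table holds whole-number counts per gene and well, and the deposited table of wells gives the percent of counts on ERCC spike-ins. Per the submitters' processing notes, the counts were made with bcl2fastq 2.20, cutadapt 2.1.0, STAR 2.7.5c and STARsolo 2.7.5c on the build GRCm38, with Seurat 2.3.4 and R 3.4.3 also listed. The annotation release, the use of strand and the collapsing of UMIs are not stated, so the counts are called UMIs here from the design of read 1. Of 52636 gene identifiers, 99.6% were found in GENCODE M21, whose coordinates are given.

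The well table labels 1612 wells as LHA, 68 as qRNA, 64 as ERCC, 21 as Empty, 19 as empty and 40 as n/a. The contents of the qRNA wells are not stated. LHA wells with at least 1000 genes, at least 2000 UMIs and at most 20% mitochondrial UMIs were kept, which left 1534 wells and dropped 78. A kept cell was called a neuron when it had UMIs of at least 5 of 8 pan-neuronal genes and fewer UMIs in each non-neuronal marker list than in the pan-neuronal list, which left 1510 neurons with 68620184 UMIs. No doublet caller was run, since wells were filled by hand, and the number of neurons in more than 1 gate is given instead. The glutamate gate took neurons with at least 2 UMIs of Slc17a6, the vesicular glutamate transporter, and Slc32a1, the vesicular GABA transporter, at no more than 20% of the sum of both. The GABA gate used the same limits with the transporters exchanged. The Hcrt gate and the Pmch gate took neurons of any transmitter gate with at least 0.2% of UMIs in that gene and more of it than of the other. Neurons were thinned to 18000 UMIs, the 10th percentile rounded down, where cells of unequal depth were compared.

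UMIs were summed per plate and class and tested with edgeR 4.0.16 (TMM, filterByExpr, robust quasi-likelihood test, plate as block) on plates with at least 5 cells in each class for the GABA and glutamate gates and at least 3 cells for the other comparisons. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with 0.05 as the threshold. Tests were two-sided, except the permutation test of the spread of shares between plates and the Poisson tests of few UMIs, which were one-sided. Fold changes are relative to the TMM scaling and so differ from ratios of CPM (counts scaled to a common library total). A log2 value is followed by an approximate standard error, and a CPM value by the SD over plates. This standard error is the absolute log2 value divided by the square root of the F statistic of the quasi-likelihood test, so it restates that test. A gene with no count in a class was given a lower bound against 3 counts over the class. For 1 to 3 counts the ratio of summed CPM is given with its exact 95% counting interval. Shares carry exact (Clopper-Pearson) 95% intervals. These cover counting error only. Medians per plate were compared by flipping signs of the plate differences, exactly under 10 plates and with 100000 permutations otherwise. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01. The p-values over plates may be too small, because 19 plates came from 7 mice and no label ties a plate to a mouse.

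Neurons were clustered with leidenalg 0.10.2 at resolution 1 on 30 neighbours, 30 components and 2000 variable genes found with scanpy 1.11.5. Genes of 6 lists of transmitter machinery, peptides and receptors were left out, as were both transporters, so that these could be compared between clusters. Each cluster was tested against all other neurons with Benjamini-Hochberg adjustment over all list genes and clusters together, and a call also needed a log2 fold change of at least 1. The clusters and the tests rest on the same cells.

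The groups, gates, tests, 24 gene lists, the rule for naming genes and 46 alternatives were fixed before the data were examined, and 14 alternatives were added later. A named gene had an adjusted p under 0.05, a log2 fold change of at least 1, at least 20 CPM in the higher class and one direction in at least 80% of plates. The 8 largest changes in each direction and up to 4 members of each list were named, without predicted and mitochondrial genes and the genes that define a gate. A fixed set of 10 genes was named in the first comparison whatever the test gave, and up to 3 genes were named per cluster. On simulated data with the same plates and depths, the test recovered 92% of genes changed 4-fold in the first comparison, 53% in the Hcrt comparison and 42% in the Pmch comparison, and 57%, 15% and 7% of genes changed 2-fold, with 10, 7 and 2 false calls. The alternatives covered DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, no plate block, thinned cells, other gates and cell minimums, single index sets and other clusterings. Barcode lists and wells labelled n/a were not used. Of 150 named genes with coordinates, 67 overlap another annotated gene, and their counts are uncertain to that extent. Pmch lies on the other strand of Parpbp. Some list members are counted in their lists but not reported here by name. The remaining computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.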

Results

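The data held 1510 neurons from 19 plates of the lateral hypothalamic area, a region of the brain that controls feeding and arousal and receives axons from the AGRP neurons of the arcuate nucleus. A plate held 44 to 86 neurons, and its LHA wells summed to between 1835746 and 5070306 UMIs. A neuron had a median of 38501 UMIs (3608 to 263078) and 4959.5 genes (1338 to 11027). Plate medians ran from 20676.5 to 95062.5 UMIs. A further 24 kept cells fell outside the neuron gate, of which 13 had most marker UMIs in the oligodendrocyte list, 6 in the mural list, 3 in the astrocyte list and 1 each in the endothelial and ependymal lists. All 6 mural-list cells and 2 of the 3 astrocyte-list cells were wells whose profile lay nearer to the qRNA wells than to neurons. Of the 13 oligodendrocyte-list cells, 11 also had at least 1% of UMIs in Hcrt. Agrp reached 12 UMIs at most in a neuron.

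Most picked neurons expressed Hcrt, the gene of the arousal peptides called orexins or hypocretins (chromosome 11, 100761069 to 100762931, GRCm38). At the 0.2% gate 1236 of 1510 neurons were in the Hcrt gate (81.9%, 95% interval 79.8 to 83.8) and 71 in the gate of Pmch (4.70%, 3.69 to 5.89), the gene of melanin-concentrating hormone (chromosome 10, 88091072 to 88092375). Hcrt UMIs were also found in wells that hold no cell. The median over 17 plates was 16.5 Hcrt UMIs in these ERCC and empty wells. It was 36 in qRNA wells, whose contents are not stated, and 51.5 in neurons outside the 1% gates. Hcrt took a median of 0.191% of the UMIs of those neurons, close to the 0.2% gate, and its source there was not settled; 211 neurons lay between 0.2% and 1%. A stricter gate at 1% took 1053 neurons for Hcrt (69.7%, 67.3 to 72.0) and 70 for Pmch (4.64%, 3.63 to 5.82). Neurons of these stricter gates gave a median of 13.6% of their UMIs to Hcrt and 17.6% to Pmch, and 3 neurons had at least 1% of both.

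**Figure D1:**
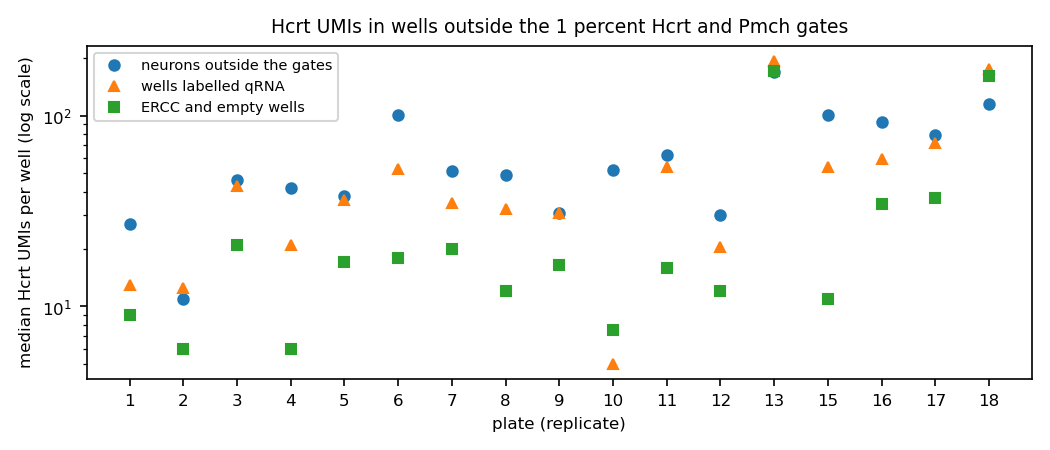
Median Hcrt UMIs per well (log axis) in each of the 17 plates with control wells, for neurons outside the 1% Hcrt and Pmch gates, wells labelled qRNA, and ERCC or empty wells. Plate medians ran from 6 to 171 in ERCC and empty wells.

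More neurons fell in the glutamate gate than in the GABA gate. The glutamate gate held 923 of 1510 neurons (61.1%, 58.6 to 63.6) and the GABA gate 121 (8.01%, 6.69 to 9.50), with 8 in both (0.530%) and 458 unassigned (30.3%, 28.0 to 32.7). Over plates the glutamate share was 60.8% ± 12.9 (SD, n = 19) and the GABA share 8.27% ± 7.43. Both shares varied between plates more than permuted gate labels allowed (permutation p = 1e-05, the smallest 100000 permutations can give). Cells were picked by hand, so the shares describe the picked cells. The GABA gate also left out neurons with GABAergic markers. In cluster 5 described below, 99.3% of 150 neurons had a Gad2 UMI, but 56 were in the GABA gate and 91 were unassigned. A UMI of Slc17a6 was seen in 69.6% of neurons (61.7% after thinning) and of Slc32a1 in 15.4% (10.8% after thinning). In the kept cells outside the neuron gate, 54.2% had a Slc17a6 UMI (13 of 24; 45.0% after thinning) and 4.17% a Slc32a1 UMI (1 of 24), at a median of 38678 UMIs. Without the 8 wells that resembled the qRNA wells, none of which had a UMI of either gene, the shares were 81.3% (13 of 16, 54.4 to 96.0) and 6.25% (1 of 16). Of these 16 wells, 13 were oligodendrocyte-list cells, and 11 of those had at least 1% of UMIs in Hcrt. The shares therefore do not give the background of the transporters in non-neuronal cells. No qRNA well had a UMI of either gene (0 of 68, which allows up to 5.28% of wells; median 18251 UMIs). The glutamate gate was largely made of Hcrt neurons, since 827 of its 923 neurons passed the 1% Hcrt gate (89.6%). Of the 121 GABA gate neurons, 120 lay outside both 1% peptide gates, although 56 passed the 0.2% Hcrt gate. With gates at 5 UMIs and none of the other transporter, the glutamate share was 40.1%, the GABA share 2.05% (31 neurons) and the unassigned share 57.7%, and with gates at 1 UMI the GABA share was 13.2% (200 neurons) and the unassigned share 17.4%.

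The first comparison asked which genes separate GABA gate neurons from glutamate gate neurons in the region that AGRP neurons innervate. Among peptide genes, GABA gate neurons had more Tac2 for neurokinin B (log2 fold change 7.90 ± 0.53 (SE, n = 11 plates), 492 ± 380 against 1.62 ± 2.80 CPM, adjusted p = 4.83e-07) and Crh for corticotropin-releasing hormone (6.58 ± 0.73, adjusted p = 4.65e-05). Gad2 and Gad1, the enzymes that make GABA, were higher by 4.81 ± 0.13 (adjusted p = 1.11e-22) and 3.17 ± 0.16 (adjusted p = 5.58e-15), each in 11 of 11 plates. Calcr, the calcitonin receptor, was higher by 5.56 ± 0.42, with 103.3 ± 67.8 against 1.81 ± 1.88 CPM. In glutamate gate neurons Hcrt reached 116321 ± 19159 CPM against 2575 ± 1526 (log2 fold change -6.09 ± 0.29, adjusted p = 4.04e-08), and Pdyn, the precursor of the opioid peptide dynorphin, followed it (-5.97 ± 0.38, adjusted p = 3.95e-07).

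In the list of neuropeptides and secreted signals, 18 members were tested, 8 were higher in the GABA gate and 7 lower. Tac1, Nts, Pnoc, Gal, Cartpt and Penk were the other 6 higher members, and Cartpt, the gene of the appetite-linked CART peptide, was higher by 3.36 ± 0.96 (adjusted p = 0.0266), though not past the threshold without replicates 14 and 19 (3.07 ± 1.08, adjusted p = 0.0848, 9 plates). Cbln1, a synapse organiser, was lower (-6.46 ± 0.31), as was Nptx2, a secreted pentraxin of excitatory synapses (-6.75 ± 0.31). The list as a whole was not called (camera adjusted p = 0.975). Transcription factors of the GABAergic lineage had 6 of 8 tested members higher and 1 lower (adjusted p = 2.53e-05), with Dlx5 at 6.55 ± 0.66, Dlx1 at 6.13 ± 0.46 and Isl1 at 4.45 ± 0.26. Both tested factors of the glutamatergic list were lower (adjusted p = 0.0064), and one of them, Lhx9, had 3 counts in the GABA gate, a ratio of 179 (61.1 to 867). Rfx4, a transcription factor, had no count in the GABA gate and was at least 200-fold lower there. Nptx2, Lhx9 and Rfx4 were also low in cluster 6 described below, which held 42 glutamate gate and 0 GABA gate neurons. Pooled CPM was 15.9, 8.86 and 10.9 in that cluster, against 256, 130 and 151 in all other neurons. Nptx2, Lhx9 and Rfx4 therefore do not mark glutamate gate neurons as a whole. GABA machinery had 2 of 4 members higher (adjusted p = 2.01e-04).

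Receptors for the outputs of AGRP neurons, which release AGRP, NPY and GABA, had 6 of 11 tested members higher in the GABA gate and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 4.90e-04). These included Gabra5 (3.92 ± 0.52) and Gabbr2 (2.53 ± 0.35), which are subunits of GABA receptors, and Npy2r (3.26 ± 0.58), an NPY receptor. Mc4r, the melanocortin receptor that AGRP blocks, was under the count filter of this test, with 333 UMIs in the GABA gate (85.1 CPM) and 15 in the glutamate gate (0.513 CPM). Lepr, the leptin receptor, had 73 and 8 UMIs, Npy1r 37 and 19, Npy5r 23 and 11, and Ghsr, the ghrelin receptor, 0 and 12. These pairs are raw UMIs and not scaled to the totals, which were much larger in the glutamate gate, as the Mc4r values show. They therefore understate the GABA gate relative to the glutamate gate, and 0 UMIs of Ghsr there do not show that it was absent. Metabolic hormone receptors had 6 of 14 members higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.0138), led by Calcr, Prlr (3.05 ± 0.52) and Nr3c1 (2.42 ± 0.24). Neuropeptide receptors had 1 of 8 higher and 5 lower (adjusted p = 0.0768), among them Trhr for thyrotropin-releasing hormone (-4.60 ± 0.48) and Crhr2 (-2.65 ± 0.42). Monoamine and acetylcholine receptors had 1 of 8 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.593), including Adra1b (-4.71 ± 0.64) and Htr1a (-3.69 ± 0.64).

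Calcium-binding proteins had 7 of 9 members lower in the GABA gate and 1 higher (adjusted p = 2.96e-05), with Calb1 at -4.35 ± 0.43 and Necab2 at -4.03 ± 0.35. Potassium channels had 13 of 28 members higher and 1 lower (13 and 2 adjusted over the list alone; adjusted p = 0.00168), such as Kcnk3 (3.16 ± 0.46) and Kcna1 (3.00 ± 0.42). Sodium, calcium and HCN channels had 10 of 27 higher and 6 lower (12 and 6 adjusted over the list alone; adjusted p = 0.0138), with Scn8a at 2.18 ± 0.23 and Cacna2d1 at -2.79 ± 0.26. Glutamate receptors had 8 of 18 higher and 1 lower (adjusted p = 2.01e-04), led by Grik3 (5.60 ± 0.63) and Grin2a (3.24 ± 0.41). Glutamate machinery had 2 of 4 members higher, Gls2 and Slc1a1, a glutaminase and a glutamate uptake carrier (adjusted p = 0.0315, and adjusted p = 0.0727 with an estimated correlation). Gls2 turned to -1.15 with neurons of the 0.2% Hcrt and Pmch gates left out and to -0.639 with the 1% gates left out, short of the threshold in both. Monoamine and cholinergic machinery had 2 of 4 lower, Ddc and Ache (adjusted p = 0.0446, and adjusted p = 0.0872 with an estimated correlation). Immediate early and dissociation genes had 4 of 13 lower, with Fos at -2.80 ± 0.43 (adjusted p = 0.0315, and adjusted p = 0.201 with an estimated correlation). The astrocyte list had 1 of 2 members higher, Aldoc, a glycolytic enzyme (adjusted p = 0.0301, and adjusted p = 0.0760 with an estimated correlation). Pan-neuronal genes had 3 of 8 higher and 5 lower, with a median of -0.40 and a mean of 0.14 (adjusted p = 0.428). Oligodendrocyte, endothelial and arcuate peptide lists had 1 tested member each, none of which passed, and no gene of the oligodendrocyte precursor, microglia, mural or ependymal lists was tested. With the classes exchanged in random plates, 17 of 39 splits also called at least 1 list.

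edgeR called 823 genes higher and 1313 lower in the GABA gate among 8666 tested (11 plates), and 868 genes met the naming criteria. With neurons of both 1% peptide gates left out and at least 3 cells per plate and class, choices made after the data were seen, 33 genes were higher and 21 lower of 3710 (9 plates, 91 and 45 cells). Changed one at a time, leaving these neurons out with at least 5 cells gave 17 higher and 16 lower (5 plates, 60 and 32 cells), and at least 3 cells with these neurons kept gave 729 higher and 1372 lower (13 plates, 119 and 570 cells). In the 9-plate comparison Nts (5.21 ± 0.92, adjusted p = 0.0327), Gal (4.50 ± 0.68, adjusted p = 0.0148), Mc4r (4.09 ± 0.71, adjusted p = 7.93e-04), Gad2 (4.50 ± 0.65, adjusted p = 0.0111) and Calcr (2.29 ± 0.59, adjusted p = 0.0355) were higher in the GABA gate, Mc4r and Calcr in 8 of 9 plates and the others in 9 of 9. Mc4r was the only receptor for AGRP neuron outputs that passed, of 8 tested; Gabbr2 was at 0.37 ± 0.48 (adjusted p = 0.910), and Gabra5 and Npy2r were not tested. Calcr was the only metabolic hormone receptor that passed, of 7 tested, with Prlr at 0.24 ± 0.54 (adjusted p = 0.965) and Nr3c1 at 1.64 ± 0.46 (adjusted p = 0.0728). Otp, a transcription factor of hypothalamic neurons, was lower by -6.34 ± 0.59 on the log2 scale (adjusted p = 1.08e-08), and Calb1 and Cacna2d1 were again lower (-2.54 ± 0.40 and -2.49 ± 0.46). The glutamate gate neurons left in the 9-plate and 5-plate comparisons came mostly from cluster 2 described below, whose leading gene was Otp (6.53 ± 0.69). Of 11 peptide genes tested, Nts, Gal and Cartpt passed; Crh was at 3.45 ± 0.93 (adjusted p = 0.196), and Tac2 was under the filter with 926 and 1 UMIs. Dlx1 and Isl1 passed of 5 GABAergic lineage factors, with Dlx5 under the filter, and 2 of 7 calcium-binding proteins were lower. No potassium channel or glutamate receptor passed, of 11 and 8 tested (median log2 fold change -0.04 and 0.40, against 0.49 and 0.46 over the 28 and 18 tested with all cells), and of 16 sodium, calcium and HCN channels only Cacna2d1 did, with 321 genes at an unadjusted p under 0.05. Hcrt was level between its classes (-0.05 ± 0.12, adjusted p = 0.967), as was Pmch (0.04 ± 0.23, adjusted p = 0.987). In the 5-plate comparison Tac2 (7.88 ± 0.59, adjusted p = 4.25e-09), Gal, Gad2, Otp, Calb1 and Cacna2d1 passed, Nts (5.68 ± 0.86, adjusted p = 0.160) and Calcr (2.49 ± 0.87, adjusted p = 0.411) did not, and Crh and Mc4r were under the filter.

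**Figure D2:**
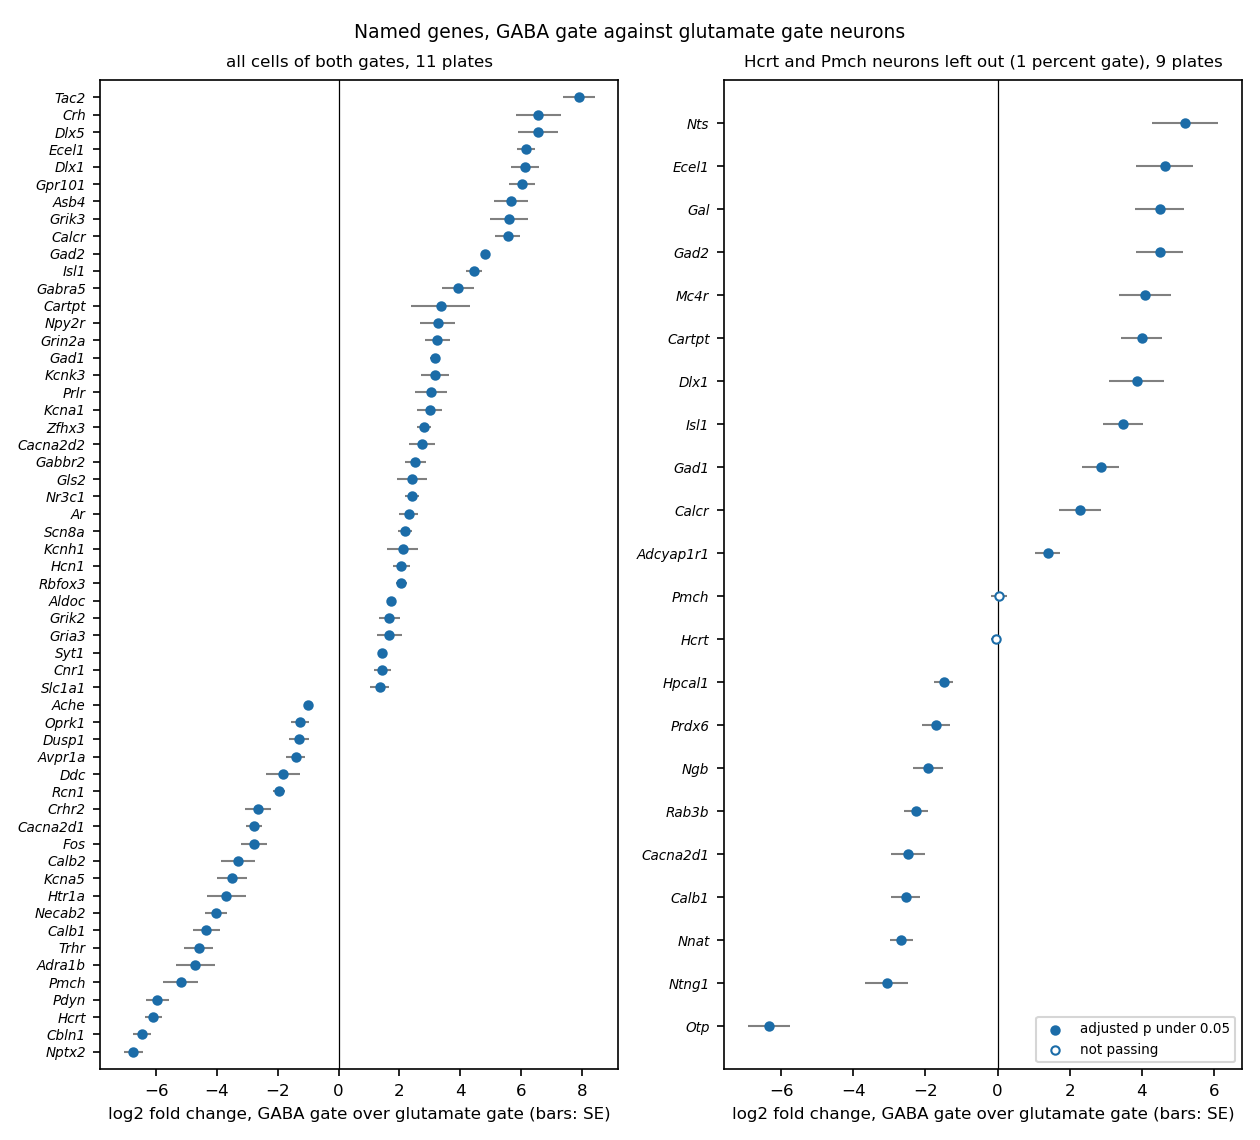
Log2 fold changes (points) with standard errors (bars) of named genes with more than 3 counts in each class, GABA gate over glutamate gate, for all cells (11 plates) and with neurons of the 1% Hcrt and Pmch gates left out and at least 3 cells per class (9 plates). Filled points had an adjusted p under 0.05. Tac2 led the first panel at 7.90 and Nts the second at 5.21.

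GABA gate neurons held fewer UMIs than glutamate gate neurons in 11 of 11 plates. Plate medians averaged 34206.9 ± 13832 (SD) and 62491.1 ± 19824.2 UMIs, a difference of -28284.2 (permutation p = 0.00076). With all 11 plates in one direction, this is the lowest p that sign flips of 11 plates can give, up to the error of random draws. At the same depth, plate medians averaged 3868.83 ± 232 genes in the GABA gate and 3837.5 ± 125 in the glutamate gate, a difference of 31.3 ± 193 (SD, n = 9 plates, exact p = 0.625). Hcrt, Scg2 and Pmch took 11.9%, 2.91% and 1.03% of all glutamate gate UMIs, against 0.434%, 0.351% and 0.0260% in the GABA gate. Equal totals therefore left fewer UMIs for other genes in the glutamate gate. Without thinning the GABA gate had fewer genes in 11 of 11 plates (difference -839, permutation p = 0.00076, again the lowest p possible up to the error of random draws). With neurons of the 1% peptide gates left out, the difference in UMIs was 2758.7 in 5 plates (exact p = 0.1875), and 5 plates are too few for an exact p under 0.05.

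**Figure D3:**
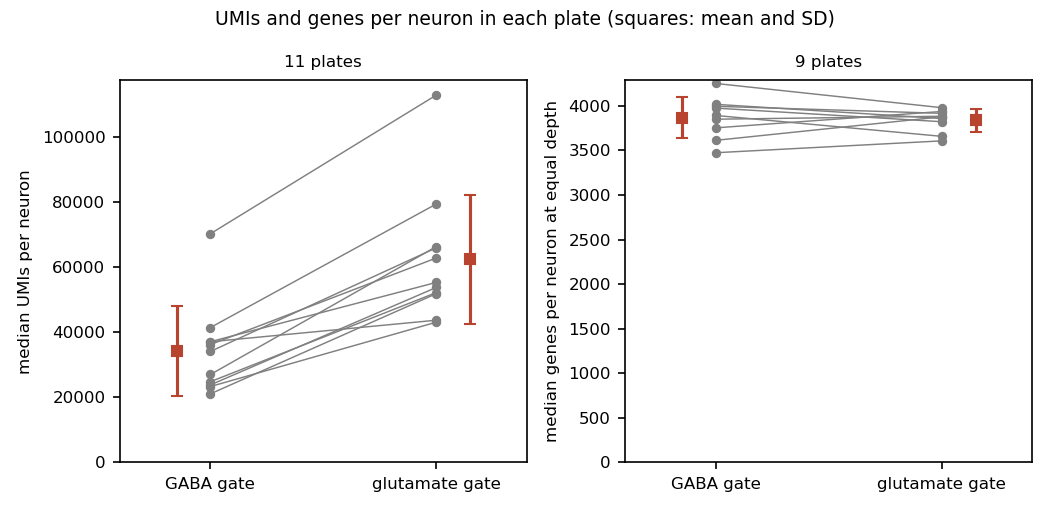
Median UMIs per neuron (11 plates) and median genes per neuron at a depth of 18000 UMIs (9 plates) in the GABA and glutamate gates. Each line joins the gates of 1 plate, and squares with bars are the mean and SD over plates.

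The next comparison asked what sets neurons of the 0.2% Hcrt gate apart from other glutamate gate neurons. Over all plates this gate held 852 glutamate gate, 56 GABA gate and 321 unassigned neurons, with 7 in both. Its limit lay near the 0.191% median of neurons outside the 1% gates, so it is not a pure set of Hcrt neurons. Over all plates, 29 glutamate gate neurons lay outside both 0.2% gates and 55 outside both 1% gates. Cluster 2 described below held 49 glutamate gate neurons and had 6 neurons in the 1% Hcrt gate. Clusters 0 and 3 had 1 and 5 neurons outside the 1% gates, clusters 1, 4 and 6 had 0, and cluster 5 had 1 glutamate gate neuron. The reference therefore came mostly from cluster 2 and does not stand for glutamate gate neurons in general. Hcrt gate neurons had more Pdyn (4.06 ± 0.36 (SE, n = 6 plates), 997 ± 126 against 83.4 ± 82.7 CPM, adjusted p = 2.97e-05), Scg2, a granin of secretory granules (3.87 ± 0.10, adjusted p = 7.36e-35), and Vgf, a secreted neuropeptide precursor (2.82 ± 0.22, adjusted p = 3.25e-15). Igfbp3, an IGF-binding protein, had no count in the reference and was at least 30.5-fold higher. The bounds were at least 10.2-fold for Thbs2, 8.44-fold for Cd44, 8.34-fold for Csrnp1 and 6.49-fold for Pcolce2. Car12, a carbonic anhydrase, had 1 count in the reference and a ratio of 65.2 (11.7 to 2579). Receptors for vasopressin (Avpr1a, 3.38 ± 0.76), dynorphin (Oprk1, 3.20 ± 0.69), IGF1 (Igf1r, 2.63 ± 0.68) and noradrenaline (Adra2a, 2.63 ± 0.73) were higher, as was the transcription factor Lhx9 (1.85 ± 0.36). Lower were Nrn1, a neurite growth factor (-7.44 ± 0.66), Otp (-6.09 ± 0.67), Sncg (-5.42 ± 0.50) and Gabbr2 (-3.05 ± 0.73). Otp and Sncg were among the leading genes of cluster 2 against all other neurons (6.53 ± 0.69 and 5.46 ± 0.65).

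By list, neuropeptides and secreted signals had 4 of 15 members higher and none lower, neuropeptide receptors 2 of 7 higher (4 adjusted over the list alone), and calcium-binding proteins 3 of 10 higher and 3 lower (6 and 3 adjusted over the list alone). GABA machinery (4 tested) and immediate early genes (12 tested) had no member that passed. The astrocyte list had 1 of 2 members lower, Aldoc (-1.46 ± 0.21), and pan-neuronal genes 2 of 8 higher and 3 lower, with Snap25 at -1.01 ± 0.14. edgeR called 403 genes higher and 124 lower of 8182 in 6 plates (294 and 27 cells), that is 76.5% higher. The DESeq2 Wald test called 410 and 249, or 62.2% higher. With the 1% gate the counts were 777 and 176 in 10 plates (475 and 48 cells), of which 464 genes were also called at 0.2%. There Otp stood at -8.12 ± 0.42, Pdyn at 3.58 ± 0.23 and Nptx2 at 4.90 ± 0.35.

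Pmch neurons were set against the same kind of reference, which came mostly from cluster 2 described below. Cartpt was higher by 6.41 ± 0.63 (SE, n = 3 plates), at 9399.6 ± 3141 against 136 ± 123 CPM (adjusted p = 5.72e-04). Gad1 was higher by 4.09 ± 0.59 (adjusted p = 0.00138), although no Pmch gate neuron was in the GABA gate. Tacr3, the neurokinin B receptor (chromosome 3, 134829007 to 134934579), had 3 counts in the reference and a ratio of 36.9 (12.5 to 180), Ramp1, a partner of calcitonin family receptors, was higher by 4.47 ± 0.90, and the GABA receptor subunits Gabrg1 (3.49 ± 0.64) and Gabra2 (2.08 ± 0.49) were higher. Igf1, the growth factor, had no count in the reference and was at least 25.7-fold higher, and Lhfp and Dmrtb1 were at least 19.6- and 19.1-fold higher. Otp, Nrn1 and Syt2 had no count in Pmch neurons and were at least 86.0-, 130- and 118-fold lower, and the channels Kcna2 (-3.48 ± 0.55), Kcnc1 (-3.48 ± 0.65) and Scn1a (-3.12 ± 0.54) were lower. Otp and Syt2 were among the leading genes of cluster 2 against all other neurons (6.53 ± 0.69 and 5.38 ± 0.42).

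By list, receptors for AGRP neuron outputs had 2 of 7 members higher, and potassium channels 2 of 14 lower (4 adjusted over the list alone). edgeR called 159 of 4405 genes in 3 plates (14 and 12 cells), of which 43 were lower and 73.0% higher, against 129 and 77 by the DESeq2 Wald test (62.6% higher). At the 1% gate the counts were 290 and 122 in 7 plates (35 and 32 cells), with Cartpt at 6.22 ± 0.70, Gad1 at 3.71 ± 0.58 and Igf1 at least 57.5-fold higher. Without replicate 3 the count was 41 genes and without replicate 4 it was 62.

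**Figure D4:**
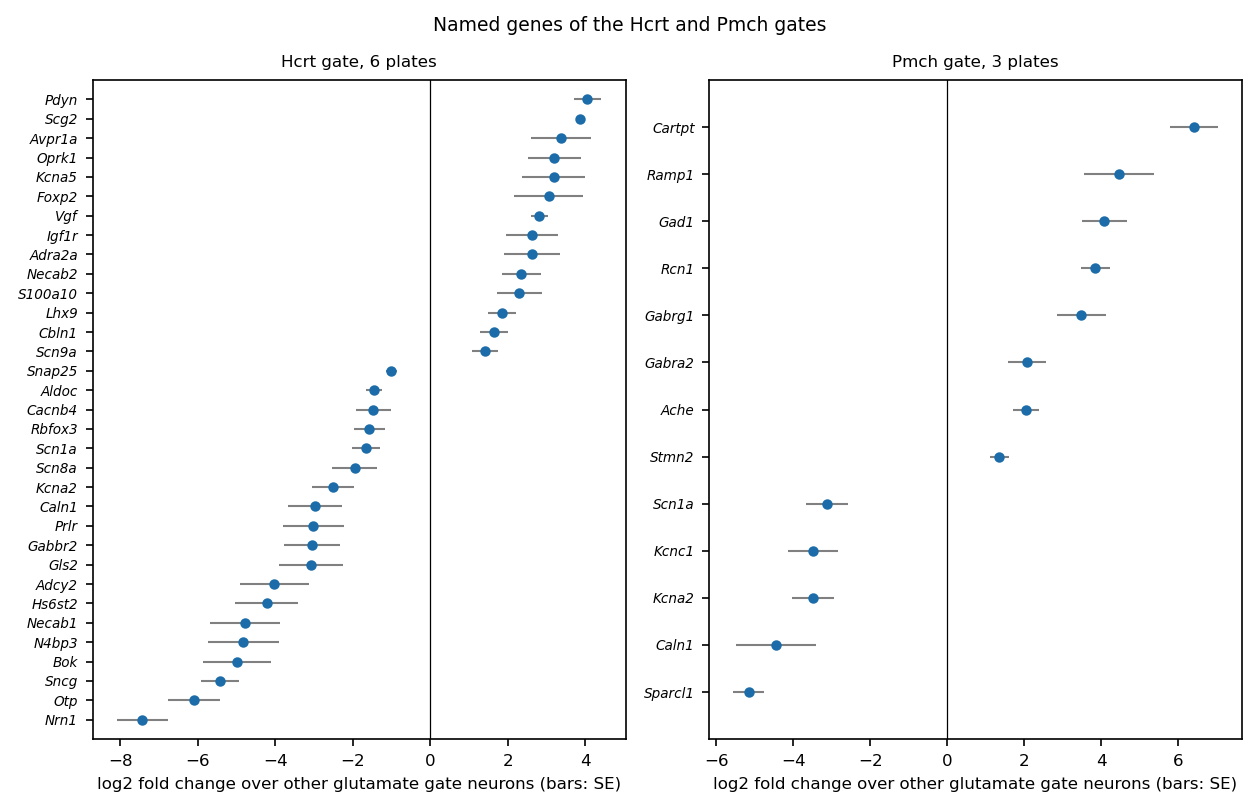
Log2 fold changes (points) with standard errors (bars) of named genes with more than 3 counts in each class, for the Hcrt gate (6 plates) and the Pmch gate (3 plates) over other glutamate gate neurons. Pdyn led the first panel at 4.06 and Cartpt the second at 6.41.

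Clustering without transmitter, peptide and receptor genes gave 7 clusters, numbered by size from 0. Clusters 0, 1, 3 and 4 (418, 256, 194 and 184 neurons) carried the markers of Hcrt neurons, cluster 6 (71) those of Pmch neurons and cluster 5 (150) those of GABAergic neurons. Cluster 2 (237) held 49 glutamate gate and 65 GABA gate neurons and had more Gad2 (2.18 ± 0.23) and Gad1 (1.45 ± 0.28) than all other neurons. The largest rises among list genes in cluster 5 were Mc4r at 6.54 ± 0.32 (SE, n = 15 plates; 139 against 1.33 CPM pooled, adjusted p = 7.46e-23) Calcr at 6.51 ± 0.27 (adjusted p = 5.44e-25) and Crh at 5.78 ± 0.71 (adjusted p = 4.77e-06). After thinning, 58.7% of its neurons had a Mc4r UMI (71 of 121, 49.4 to 67.6), against 0.264% of cluster 0 (0.00668 to 1.46) at the same depth. Mc3r (5.30 ± 0.46), the other brain melanocortin receptor, Nts (5.11 ± 0.23), Tac1 (5.10 ± 0.62) and Cartpt (3.81 ± 0.71) were also higher in cluster 5, and Cckar, Trhr, Crhr2 and Igf1r were among its lower receptors.

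Cluster 2 had more Tac2 (5.97 ± 0.69, n = 17 plates, adjusted p = 1.50e-06), Pnoc, the nociceptin precursor (4.70 ± 0.39), and Prlr, the prolactin receptor (2.97 ± 0.38). After thinning, 35.6% of its neurons had a Tac2 UMI (63 of 177, 28.6 to 43.1) and 30.5% a Pnoc UMI (54 of 177, 23.8 to 37.9). Outside the compared lists, its leading gene was Otp (6.53 ± 0.69). Cluster 2 held neurons of both transmitter gates, so these genes do not describe all of it. Cluster 6 had more Pmch (9.11 ± 0.36, n = 13 plates), Tacr3 (8.55 ± 0.30) and Ramp1 (4.05 ± 0.25). Of the Hcrt clusters, each against all other neurons, cluster 1 had more Ramp3 (3.35 ± 0.36, n = 19 plates), Hcrtr2, an orexin receptor (1.73 ± 0.37), and Cbln2 (1.66 ± 0.13). Cluster 3 had more Oprk1 (1.74 ± 0.11) and Pdyn (1.19 ± 0.09), cluster 0 more Crhr2 (1.21 ± 0.12) and Cckar (1.04 ± 0.17), and cluster 4 more Bdnf, a neurotrophin (1.21 ± 0.12). Bdnf was also called higher in cluster 1. Against the other Hcrt clusters, Pdyn in cluster 3 (0.67 ± 0.04) and Crhr2 (0.70 ± 0.12) and Cckar (0.51 ± 0.15) in cluster 0 were under a log2 fold change of 1. In all, 409 tests on 70 genes gave 62 higher and 122 lower calls, and 42 genes were higher in at least 1 cluster.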

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

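The tests on Hcrt UMIs outside the Hcrt gate, on WPRE and on the unlike LHA wells, as well as the splits of the plates, were chosen after the results were seen.

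Hcrt UMIs appeared in wells that hold no cell, outside the comparisons, with a median over 17 plates of 16.5 in ERCC and empty wells, which argues against expression by the neurons outside the 1% gate as the whole source of their Hcrt. Free RNA picked up with each cell is argued against as the whole source by the same wells, in which no cell was picked and whose lowest plate median was 6, while the qRNA wells decide nothing because their contents are not stated. Transcripts passed between wells of a plate may contribute, but this stays open: plates with more Hcrt in cell-free wells had more in these neurons (Spearman rho 0.626, permutation p = 0.00828; Pearson r 0.781, permutation p = 0.00018; n = 17 plates). Without replicates 13 and 18, rho was 0.455 (permutation p = 0.0900) and r was 0.526 (permutation p = 0.0420), and within index sets of 3 to 5 plates the rank correlation was 0.355 (permutation p = 0.244), so a difference between the sets is not ruled out. Low expression of Hcrt by some of these neurons stays open too.

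WPRE, an element of the Ai9 reporter allele, is outside the comparisons and had 976 UMIs in LHA wells although cells were picked as non-fluorescent, and none in qRNA or ERCC wells (3 in the Empty well described below). A few strongly labelled wells do not account for it, since the top 17 wells held 15.7% of its UMIs. A mouse transcript shared with the qRNA wells is argued against by 18.1 UMIs expected there and 0 found (Poisson p = 1.36e-08). Passing between the wells of a plate as the whole source is argued against as well, since 25.0 UMIs would lie in ERCC and empty wells if WPRE spread as Hcrt did, and 0 were found, or 3 with that Empty well counted, which was left out of the expected number (Poisson p = 4.01e-08). Low transcription of the allele in every cell type may be the source, as the lowest level in a cluster was 8.44 CPM. The fluorescent reporter of the same allele, tdTomato, had 15 UMIs in 9 LHA wells. Whether these libraries count both parts of the allele equally was not tested, so the tdTomato count does not decide the source, which stays open.

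In data outside the comparisons, 8 LHA wells on replicates 14 and 19 were nearer to the profile of the qRNA wells than to that of neurons. Their lowest correlation with the qRNA profile was 0.574, and these 2 plates have no wells labelled as controls, so mislabelled control wells are a candidate explanation. Picked cells of the non-neuronal kinds seen elsewhere are argued against, because the highest such correlation among other LHA wells outside the neuron gate was 0.300, in a well of replicate 18 (4522 UMIs) that was also nearer to the qRNA profile than to neurons (0.207). All 8 were kept and none entered the neuron gate, so they entered no gene comparison but were among the 24 kept cells outside the gate. Beyond the kind of cell, no biological explanation was tested.

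A well marked Empty on replicate 15 held 100707 UMIs and 5653 genes, against at most 1022 UMIs in other empty wells.

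Other splits exchanged the classes within plates. For the GABA and glutamate gates, 1 of the 40 splits, the real one, gave as many as 2136 genes, and the highest other gave 1112. These gates were set by expression in the same cells, and exchanging whole classes turns a class difference into spread between plates. Low counts in the other splits therefore do not exclude chance. For gene lists the real split gave 13 and the highest other 11 (1 of 40), with the same limit. A single list is not set apart from chance either, because 17 of the 39 other splits called at least 1 list, 16 of them with no gene called and up to 7 lists. For the Hcrt gate, 1 of the 32 splits gave as many as 527 genes and the highest other gave 4, and the limit of the GABA and glutamate splits applies here too. For the clusters the real split gave 42 genes and the highest other 1 (1 of 21), but the clusters were made from the same cells, so these splits cannot test chance. For the Pmch gate, 4 splits are too few for a share under 0.05 (real 159, highest other 0, 1 of 4 as large).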

How the results depend on the processing

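The alternatives that left out neurons of the 1% peptide gates or lowered the cell minimum of the first comparison to 3 were chosen after the results were seen. Of 72 values of the main results under alternatives, 48 kept their direction and size class, 21 moved and 3 reversed. All 49 values of 17 cluster genes kept direction and threshold under DESeq2 size factors, no plate block and without replicates 14 and 19. Other clusterings were compared by counts only, with 60 higher and 92 lower calls in 5 clusters at resolution 0.5, 94 and 177 in 11 clusters at resolution 2, and 63 and 119 in 7 clusters with list genes kept, against 62 and 122. Of 902 values of 60 genes of the first comparison, 720 did so, 177 lost the threshold and 5 reversed. Of 388 values of 42 genes of the Hcrt comparison 42 lost it, with 20 of 38 under a reference without Pdyn and 11 of 29 with thinned cells, and of 338 values of 29 genes of the Pmch comparison 46 lost it, with 19 of 29 without replicate 3 and 10 of 27 without replicate 4.

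The 2136 genes of the first comparison became 1183 with thinned cells (9 plates), 43 with gates at 5 UMIs (2 plates), 15 with 0.2% Hcrt and Pmch gate neurons left out (3 plates), 54 with the 1% gates left out and at least 3 cells (9 plates), 33 with the 1% gates left out (5 plates), 2101 with at least 3 cells (13 plates), 1293 with at least 10 cells (5 plates), and 694, 477, 819 and 554 in single index sets of 2 to 4 plates. DESeq2 size factors gave 2136 and its Wald test 2612. The 527 genes of the Hcrt comparison became 149 with thinned cells (4 plates), 953 at the 1% gate (10 plates) and 230 with a reference without Pdyn (3 plates). The 159 genes of the Pmch comparison became 251 with no filter, 1.0e+02 with thinned cells (62 higher and 41 lower, 2 plates) and 412 at the 1% gate (7 plates), and ranged from 41 (without replicate 3) to 1.2e+02 (85 higher and 32 lower, without replicate 8) when one replicate was left out. The 0.1% gate left 1 plate for Hcrt and 0 for Pmch and gave no value.

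The difference in genes per cell reversed to -839 without thinning, where depth differed, and to -65.5 without the 1% gates (3 plates). The difference in UMIs reversed to 2758.7 without the 1% gates. The glutamate share was 40.1% with gates at 5 UMIs, the unassigned share 57.7%, or 17.4% with gates at 1 UMI, and the GABA share 2.05%, or 13.2% with gates at 1 UMI, against 8.01%. Without the plate block the pan-neuronal list (adjusted p = 0.499) and the neuropeptide list (adjusted p = 0.498) changed direction, uncalled in both cases; the cause was not tested. With 0.2% gate neurons left out, Hcrt was at 0.0634 and Gls2 at -1.15, with the 1% gates left out and at least 3 cells Pmch was at 0.0379, and with the 1% gates left out Pmch was at 0.334 and Gls2 at -0.639. For Hcrt and Pmch the removal itself takes away the difference; for Gls2 the cause was not tested. Mc4r and Lepr were under the filter of the first comparison.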

Other observations

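The comparison of Hcrt clusters with each other was added after the clusters were seen. Nts, the neurotensin precursor, was higher in cluster 1 by 4.90 ± 0.43 (SE, n = 19 plates), in 19 of 19 plates. Ramp1 (3.57 ± 0.34), Cbln2 (2.97 ± 0.16) and Gad2 (2.17 ± 0.34) were also higher, and Oprk1 (-2.40 ± 0.18) and Crhr2 (-1.24 ± 0.17) were lower. Cluster 3 had more Fgfr1, a growth factor receptor (1.63 ± 0.25), and Oprk1 (1.54 ± 0.11), and less Nts (-5.09 ± 0.22), Gad2 (-4.30 ± 0.43) and Bdnf (-2.91 ± 0.31). Cluster 0 also had less Nts (-3.61 ± 0.57), Gad2 (-2.01 ± 0.46) and Bdnf (-1.22 ± 0.18), and cluster 4 less Nts (-4.06 ± 0.28). Cluster 4 had more Bdnf (1.04 ± 0.11), and so did cluster 1 (0.97 ± 0.10), just under the log2 fold change of 1 that a call needed. In all, 198 tests gave 10 higher and 21 lower calls. The clusters were made from the same cells, so these p-values do not test whether the clusters exist.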
